A study of Homo sapiens with 15 samples.

How the data were processed

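The deposited table holds raw read counts per gene, which the authors made from their RNA-seq reads. Per the submitters' processing notes the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.22.5, with the genome build hg38. The notes give no role or setting for each tool, and strand handling is not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be shared. Per the labels' protocols the libraries were made after poly(A) capture or rRNA removal, and which of these was used for each library is not stated. All 58735 gene identifiers were found in GENCODE release 29, which gave gene names and hg38 coordinates. Y-linked genes, XIST and TSIX (520 genes) were left out of every step.

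The labels describe 15 samples in 5 groups of 3. Columns were matched to samples by name. The column names of the CD41 group occur a second time in the table, with identical values. The second copy was not used, which leaves 3 unused columns, and no column was matched to the CD34 group, so its 3 samples were not analysed here and 12 libraries in 4 groups were. Comparisons with CD34 that had been planned were therefore not made, and the sets of M07e genes were taken from the comparison with CD41 alone. M07e_C was taken as the control of the knockout because its title pairs with M07e_KO. The labels do not say what the C stands for.

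For each comparison the 6 libraries were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, the quasi-likelihood F test, and a Benjamini-Hochberg FDR under 0.05. Printed values are CPM with TMM factors over all 12 libraries. A count of 0 allows up to 3 counts, which is 0.102 to 0.627 normalised CPM in a single library. Floors and intervals cover counting error only, since no molecular identifiers are recorded. Total counts were 15303398 to 28427274. The common biological coefficient of variation was 0.579 for M07e against CD41, 0.055 for M07e_KO against M07e_C and 0.252 for M07e_C against M07e.

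Gene lists were fixed before the data were examined: 23 lists, with 598 of 601 symbols matched. They cover megakaryocyte and platelet proteins, megakaryocyte and erythroid transcription factors, erythroid, granulocyte and monocyte, mast cell, basophil and eosinophil, lymphoid, stromal and endothelial, and stem and progenitor genes. Others cover genes known from C/G leukaemia, DNA methylation, class II antigen presentation, interferon, JAK-STAT, p53, BCL2, BMP and TGF-beta, hedgehog, HOX, imprinted, germline, neural and adhesion, proliferation and ribosome biogenesis genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM, and also with an estimated correlation and with fry, which asks whether a list's genes move 1 way on balance and does not compare them with other genes. The rule for named genes was also fixed before. It took DNMT3B, then per comparison of the study the 10 protein-coding genes with the largest rise and the 10 with the largest fall. These had to have an FDR under 0.05, a mean of at least 10 in the higher group and no overlap of replicates. It then took 2 to 4 members of each list, by the smallest FDR in each direction or for going against the majority. The markers CD34, ITGA2B, ITGB3, GLIS2 and CBFA2T3 came last. The part on list members was not followed throughout. Some lists have no member named in a comparison. MPO was named in M07e against CD41 while TYROBP, of the same list and with a lower FDR, was not. Further genes named for M07e_C against M07e, and those in the closing section, were chosen after their values were seen.

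The pipeline was tested on simulated data drawn from the real means, library sizes and spread, with 200 changed genes. Counts were drawn independently per gene, with the same dispersion in every library. A single outlying library was therefore not modelled, as CD41 replicate 2 is in the real data. Its Pearson's r with replicate 1 was 0.6488, where replicates 1 and 3 had 0.9918. The shares recovered may thus not hold for the real M07e and CD41 libraries. In M07e against CD41 edgeR recovered 0 of the 50 genes at each of the 1.5-, 2-, 4- and 8-fold changes among 14362 genes. To tell a fault from a lack of power, 2 more settings were added after that result. With the dispersion set to 0.05, 94% of the 4-fold and 94% of the 8-fold changes were recovered. With 3000 changed genes at the real spread, 29.5% of the 4-fold and 66.5% of the 8-fold changes were. In the planned setting 4.64% of the unchanged genes had p under 0.05 and the median estimate of the 4-fold changes was 1.99 on the log2 scale, so the script gave the right sizes. In data simulated this way the comparison detects mainly large changes, and only when many genes change. DESeq2 1.42.0 recovered 62 of those 200 genes there with 83 false calls among 145. DESeq2 was not simulated with 3000 changed genes, so how reliable its calls are on the real data was not tested. In M07e_KO against M07e_C edgeR recovered 74% of the 1.5-fold and 94% of the 4-fold changes among 13698 genes. In M07e_C against M07e it recovered 12% of the 2-fold, 62% of the 4-fold and 88% of the 8-fold changes among 14689 genes.

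Alternatives fixed before the data were examined were RLE factors, library size alone, no filter or a CPM filter of 1 in 3 libraries, DESeq2, a minimum absolute log2 fold change of 1, a fit of all libraries, the replicate number as a block, and each library left out. For the knockout they also included the libraries titled M07e as control, alone or with M07e_C. Added after seeing the data were fits without replicate 3 of CD41 and of M07e together, with CD41 replicate 1 alone, without mitochondrial genes, and without genes near 0 in a group of the knockout comparison. No pair of libraries of a group agreed within sampling noise. The lowest median chi-square per gene for a pair was 0.919, against 0.455 expected, so no library was counted as a copy of another. Figures were drawn with matplotlib 3.10.9.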

Results

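RNA sequencing gave read counts per gene for 12 libraries in 4 groups of 3 replicates. M07e is a human megakaryoblastic leukaemia cell line that carries the CBFA2T3-GLIS2 fusion (C/G) and was cultured with GM-CSF. The group titled CD41 holds megakaryocyte progenitors derived in culture from cord blood CD34+ cells. The groups titled M07e_C and M07e_KO are the M07e libraries labelled wild type and DNMT3B knockout in a CRISPR experiment. The CD34 group of the labels was not analysed here. Total counts ranged from 15303398 to 28427274 per library. Values below are normalised CPM (read counts scaled to library size with TMM factors over the 12 libraries) as mean ± SD with n = 3, and tests are edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. Nothing in the labels says that replicates came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

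The replicates of CD41 and M07e differed among themselves. Mitochondrial transcripts took 78.54% of the counts of CD41 replicate 2, against 7.29% and 13.75% in the other CD41 libraries. ITGB3 (integrin beta 3 of the platelet fibrinogen receptor) stood at 11.3 in CD41 replicate 2 and at 1121 and 1011 in the others. ITGA2B, which encodes CD41 itself, stood at 429 there and at 5123 and 5090 in the others. M07e replicate 3 lay between M07e replicates 1 and 2 for 84.5% of 10001 genes, where chance gives 33.3%. M07e replicate 3 may therefore not be an independent replicate, and the SD and p-values printed with n = 3 for M07e would then understate the spread. In CD41, replicate 2 stood apart and was in the middle for 3% of 10849 genes, replicate 1 for 31.3% and replicate 3 for 65.7%. Whether CD41 replicate 3 is an independent replicate is therefore not settled either. Pearson's r between replicates, across genes on log2 values, was 0.9972 to 0.9976 within M07e_C and 0.9968 to 0.9976 within M07e_KO. It fell to 0.9301 between M07e replicates 1 and 2 and to 0.6488 between CD41 replicates 1 and 2. Genes are not independent replicates in such a correlation.

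DNMT3B (ENSG00000088305, a de novo DNA methyltransferase, hg38 chromosome 20, 32762385 to 32809356, plus strand) was the target of the knockout. Its level was 109.7 ± 7.24 in the libraries labelled M07e_KO and 112.8 ± 7.08 in M07e_C, a log2 difference of -0.07 ± 0.06 (SE) with an edgeR adjusted p of 0.433. A count summed over the whole gene does not show whether the coding frame was broken, so it does not check the labels. The level was 68.07 ± 15.4 in M07e and 112.2 ± 75.2 in CD41. The difference between M07e and CD41 did not pass with all 6 libraries (edgeR adjusted p = 0.439). The CD41 spread came from replicate 2, the library with low ITGB3 and ITGA2B, at 25.48 against 160.3 and 150.8 in replicates 1 and 3. The M07e libraries had 83.52, 52.8 and 67.9, so CD41 replicate 2 lay below all of them and the other CD41 libraries lay above. DNMT3B was higher in M07e_C than in M07e, by 0.75 ± 0.17 on the log2 scale (edgeR adjusted p = 0.00823). With M07e as control it was likewise higher in M07e_KO, by 0.7 on the log2 scale (edgeR adjusted p = 0.0123).

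**Figure D1:**
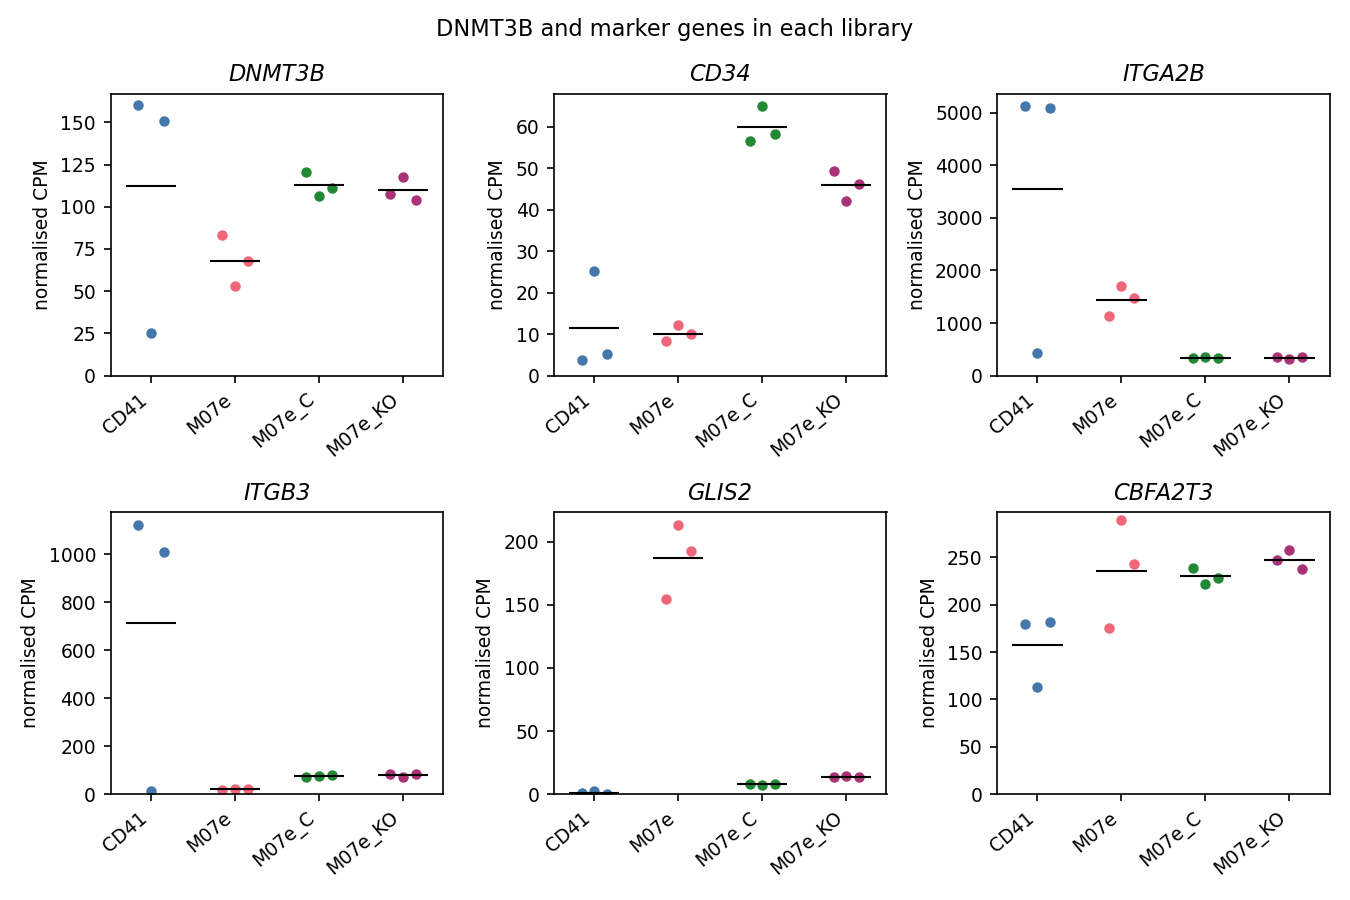
Normalised CPM (vertical axes, linear, from 0) of DNMT3B and 5 marker genes in each of the 3 libraries (points) of 4 groups, with the group mean as a line. DNMT3B lay between 103.9 and 120.5 in the M07e_C and M07e_KO libraries, and GLIS2 between 154.9 and 212.8 in the M07e libraries.

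M07e was compared with CD41 to see how the leukaemia line differs from normal megakaryocyte progenitors. In M07e 9 of 15 tested genes known from C/G leukaemia were higher, and 20 of 28 granulocyte and monocyte genes, 10 of 27 megakaryocyte and platelet proteins and 9 of 11 class II antigen presentation genes were lower. As lists they passed camera with a preset correlation only, and with an estimated correlation their adjusted p was 0.13, 0.629, 0.736 and 0.576. GLIS2, the 3' partner of the fusion, stood at 186.8 ± 29.4 in M07e and 1.299 ± 1.25 in CD41. NCAM1, the adhesion molecule CD56, stood at 399 ± 97.4 and 0.4337 ± 0.71. PF4, a platelet alpha granule chemokine, stood at 1.2 ± 0.357 in M07e and 5329 ± 4560 in CD41, and its call was lost when a library was left out (edgeR adjusted p up to 0.0757). CBFA2T3, the 5' partner of the fusion, stood at 236 ± 57.2 and 158.1 ± 39 and did not pass. ITGB3 narrowly missed the threshold (edgeR adjusted p = 0.0514), at 20.32 ± 2.36 in M07e and 714.3 ± 611 in CD41.

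Of 14362 genes tested in that comparison, 1316 were higher and 1543 lower in M07e at an edgeR FDR under 0.05. Scaling by library size alone turned this split to 2001 higher and 940 lower. The counts rested on single libraries: without CD41 replicate 2 they were 3894 and 4317, without M07e replicate 3 they were 165 and 269, and without CD41 replicate 3 they were 338 and 785. They were 500 and 1179 without CD41 replicate 1, 644 and 719 without M07e replicate 1, and 382 and 506 without M07e replicate 2. With replicate 3 of both groups left out, an alternative added after seeing the data, edgeR called 0 genes in either direction, with 2246 genes at an unadjusted p under 0.05. DESeq2, run on all 6 libraries only, called 2285 and 3454.

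The 10 protein-coding genes with the largest rise in M07e had 0 reads in all CD41 libraries. Bounds below use 3 counts over the group of 3 libraries, and they cover counting error only. PITX1, a homeobox transcription factor, stood at 236.9 ± 126 in M07e, at least 3960-fold higher. SOX11, a neural transcription factor, stood at 155.4 ± 41.1 (at least 2600-fold higher) and GSX2, a homeobox gene of the forebrain, at 118.4 ± 22.4 (at least 1980-fold higher). ROBO2, an axon guidance receptor, stood at 76.8 ± 9.97 and was at least 1280-fold higher. The others were KIF1A, KIAA1217, CLEC2A, PCDH10, LSAMP and GOLGA8M, with means from 27.25 to 162.7. KIF1A lost its call when a library was left out (edgeR adjusted p up to 0.0524), as did LSAMP (up to 0.0607).

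The 10 largest falls were LTBP1, F13A1, ELANE, HBD, CD36, TREML1, PTPRJ, PPBP, ABCC3 and RGS6. F13A1 (coagulation factor XIII A) stood at 1182 ± 971 in CD41 with 0 reads in M07e, at least 24400-fold lower. ELANE (neutrophil elastase) stood at 722.7 ± 659 in CD41 with 0 reads in M07e, at least 14900-fold lower. CD36, a scavenger receptor, stood at 369.6 ± 157 in CD41 and was at least 7640-fold lower. PPBP, a platelet chemokine, stood at 5276 ± 4520 in CD41 and 0.1619 ± 0.181 in M07e. Leaving out a library ended the calls of LTBP1, F13A1, HBD, TREML1, PTPRJ, PPBP, ABCC3 and RGS6, with edgeR adjusted p of up to 0.0944, while ELANE and CD36 passed in each such fit.

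Among the gene lists fixed before the data were examined, 9 of 15 tested genes known from C/G leukaemia were higher in M07e and 0 lower (12 and 0 adjusted over the list alone). Besides GLIS2 and NCAM1 they included GATA3, a transcription factor (182.6 ± 94.5 against 2.493 ± 1.46), and PCDH19, a protocadherin (130.8 ± 104 against 0.04081 ± 0.0707). That list came from studies that used M07e among other samples, so its direction is not independent evidence. Of 28 granulocyte and monocyte genes, 20 were lower and 0 higher (23 and 0 over the list alone). PRTN3 (proteinase 3) stood at 0.5737 ± 0.284 in M07e and 759.1 ± 702 in CD41, and MPO (myeloperoxidase) at 58.92 ± 27.1 and 3904 ± 5560. MPO was lost when a library was left out (edgeR adjusted p up to 0.13). CD41 replicate 2 had the highest levels of most of these genes, with a list median 4.03 log2 units above the other CD41 libraries once mitochondrial genes were left out.

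Of 27 megakaryocyte and platelet proteins, 10 were lower in M07e and 0 higher (17 and 0 adjusted over the list alone). These genes stood 6.03 log2 units lower in the median in CD41 replicate 2 than in the other CD41 libraries. Of 11 class II antigen presentation genes, 9 were lower and 0 higher (11 and 0 over the list alone), and with mitochondrial genes left out the list median was 2.95 log2 units higher in CD41 replicate 2 than in the other CD41 libraries. CD74, the invariant chain, stood at 0.169 ± 0.114 in M07e and 300.1 ± 116 in CD41. Of 32 interferon-stimulated genes, 11 were lower, among them IFITM3 (0.4319 ± 0.104 against 113 ± 49) and ISG15, and 1, BST2, was higher (430.6 ± 54.5 against 29.73 ± 32.7), with 15 and 2 adjusted over the list alone. BST2 lost its call when a library was left out (edgeR adjusted p up to 0.0868). The list of mast cell, basophil and eosinophil genes had 6 of 17 lower, including HDC, which makes histamine, and EPX, eosinophil peroxidase, and 0 higher (10 and 0 over the list alone). Leaving out a library ended the calls of HDC (edgeR adjusted p up to 0.102) and EPX (up to 0.162). Their CD41 levels rested on replicate 2, with 1779 for HDC against 32.68 and 86.96, and 1421 for EPX against 1.675 and 50.97. HOX genes and cofactors had 5 of 8 lower, such as HOXB2 and MEIS1, and 0 higher (5 and 0 over the list alone), and MEIS1 was lost when a library was left out (edgeR adjusted p up to 0.143). Ribosome biogenesis genes had 4 of 25 higher, such as NOLC1 (242.6 ± 54.9 against 83.33 ± 15.8), and 0 lower (3 and 0 over the list alone). NOLC1 was lost when a library was left out (edgeR adjusted p up to 0.106).

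These 8 lists passed camera with a preset inter-gene correlation of 0.01, with adjusted p from 2.01e-09 for granulocyte and monocyte genes to 0.0448 for HOX and for ribosome biogenesis genes. None of the 8 held with an estimated correlation, where the lowest adjusted p was 0.13, for the C/G and the interferon lists. The other lists did not pass. Counts of members higher and lower were 3 and 5 of 20 megakaryocyte and erythroid transcription factors, 0 and 5 of 12 erythroid genes, 3 and 9 of 21 stem and progenitor genes, and 2 and 5 of 25 cytokine-induced JAK-STAT targets. They were 3 and 4 of 28 DNA methylation enzymes and readers, 1 and 0 of 30 proliferation genes, 6 and 2 of 23 p53 targets, 2 and 0 of 15 BCL2 family regulators, and 3 and 2 of 21 BMP and TGF-beta genes. They were 2 and 1 of 8 hedgehog genes, 1 and 3 of 15 imprinted genes, 4 and 2 of 8 neural and adhesion genes, 3 and 4 of 11 lymphoid genes, and 1 and 1 of 11 stromal and endothelial genes. Too few germline genes were expressed for a test.

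Within those lists, GATA1, the erythroid and megakaryocyte factor, stood at 4.312 ± 0.851 in M07e and 405.6 ± 335 in CD41, and NFE2 at 12.01 ± 5.68 and 638 ± 149. RUNX1 was higher in M07e, at 735.9 ± 280 against 229.4 ± 39.1. GATA1 and RUNX1 lost their calls when a library was left out (edgeR adjusted p up to 0.0969 and 0.131). KIT, the stem cell factor receptor, stood at 1302 ± 151 against 77.72 ± 5.01, and MYC at 1094 ± 77.5 against 113.9 ± 29.2. SOCS3, a feedback inhibitor of cytokine signalling, was lower, at 2.817 ± 0.395 against 43.62 ± 7.69.

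**Figure D2:**
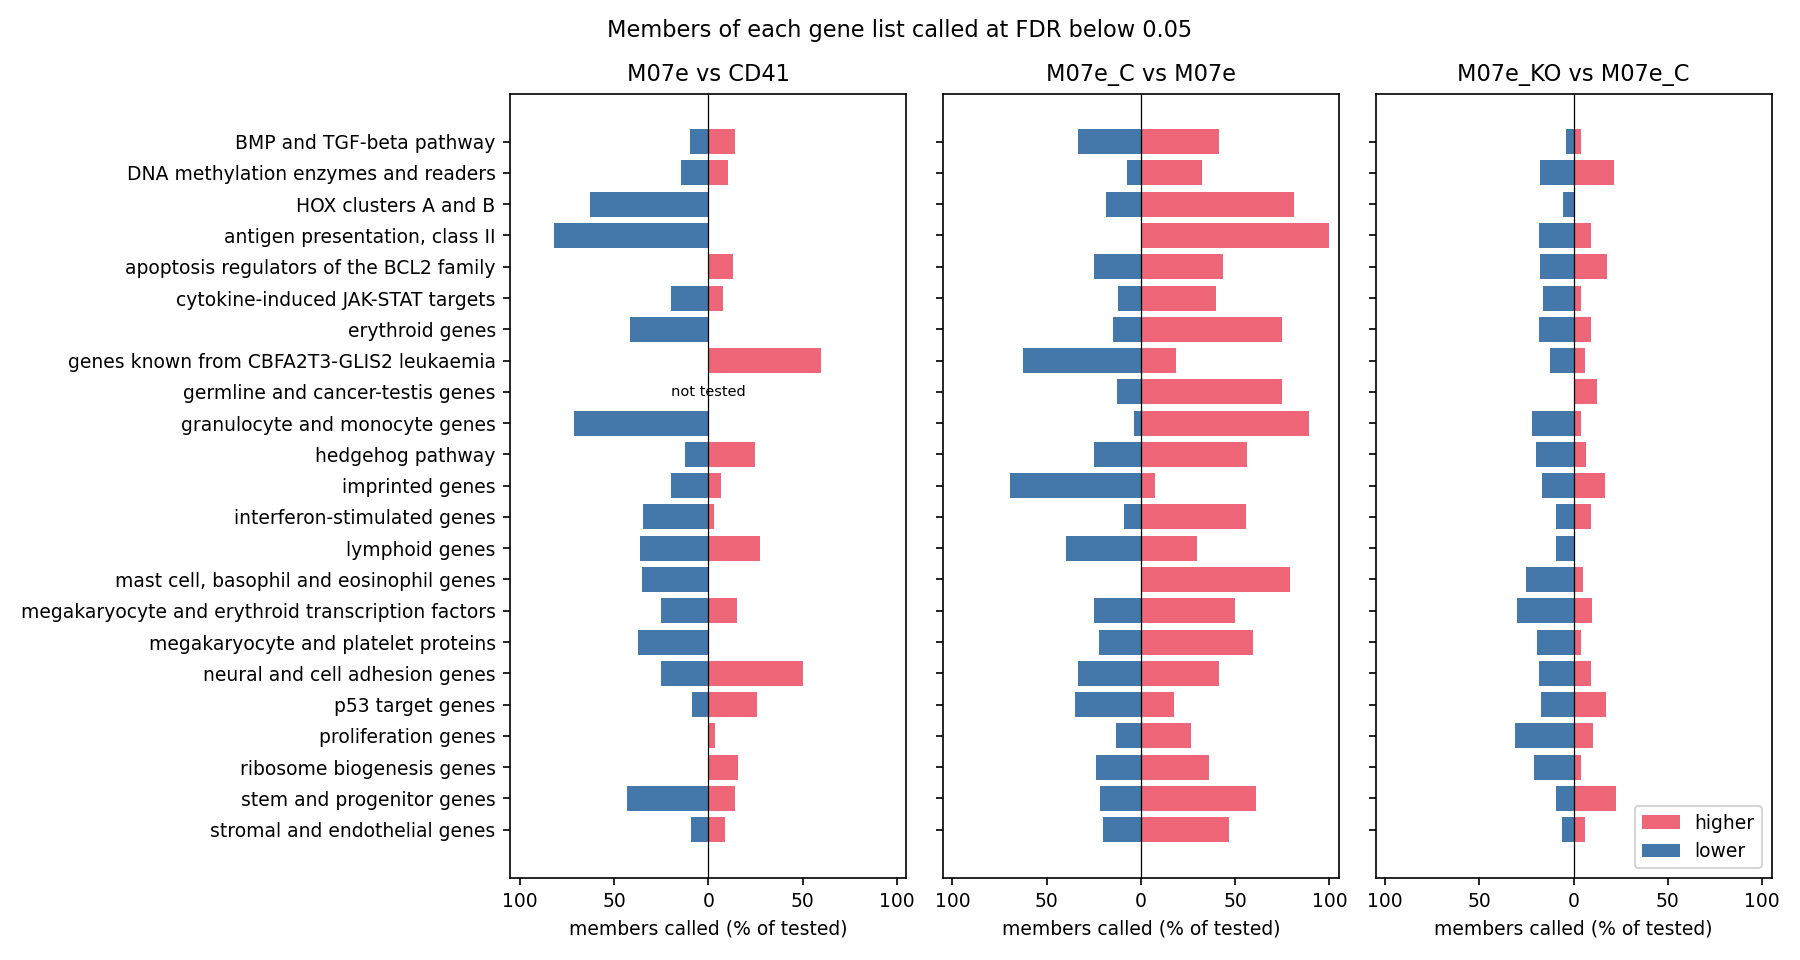
Percentage of tested members of each gene list called higher (red, to the right) or lower (blue, to the left) at an edgeR FDR under 0.05 in 3 comparisons. Of 27 granulocyte and monocyte genes, 24 were higher in M07e_C than in M07e, and of 28 such genes 20 were lower in M07e than in CD41.

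The libraries titled M07e_C and M07e carry the same line and genotype in the labels, so their comparison shows how far the sets of libraries differ without the knockout. In M07e_C 24 of 27 granulocyte and monocyte genes, 15 of 19 mast cell, basophil and eosinophil genes, 16 of 27 megakaryocyte and platelet proteins (with 6 lower) and 11 of 11 class II genes were higher, and 10 of 16 genes known from C/G leukaemia were lower. With an estimated correlation the first list passed camera (adjusted p = 0.0469) and the next 3 did not (0.228, 0.223 and 0.0575), and the C/G list did not pass with the preset correlation either (adjusted p = 0.092). PRTN3 stood at 702.6 ± 22.2 in M07e_C and 0.5737 ± 0.284 in M07e, CD74 at 934.9 ± 47.6 and 0.169 ± 0.114, PF4 at 576.6 ± 7.11 and 1.2 ± 0.357, and EPX at 524.1 ± 4.51 and 0.6926 ± 0.457. GLIS2 stood at 7.864 ± 0.721 in M07e_C against 186.8 ± 29.4 in M07e, and NCAM1 at 35.2 ± 2.81 against 399 ± 97.4. PITX1 stood at 303.3 ± 5.94 against 236.9 ± 126 and did not pass (edgeR adjusted p = 0.407). Of 14689 genes tested by edgeR, 4576 were higher and 4402 lower in M07e_C, which is 61.1% of the genes. Without M07e replicate 1 the counts were 6098 and 6114. The 10 largest rises were ELANE (759.9 in M07e_C, at least 15700-fold), EMB, DOCK2, F13A1, LTBP1, TRIB3, PRDX2, FLT3, a receptor tyrosine kinase often mutated in leukaemia, MS4A6A and ANXA2, all with 0 reads in M07e. The 10 largest falls were SLC39A3 (362.3 in M07e, at least 8590-fold), KMT2D, MYO15B, RPL23, ELAVL1, EPS15, GLRX5, ZBTB11, POU4F1 and ATG14, all with at most 1 read in M07e_C. Of these 10 genes all but POU4F1 and ATG14 met the rule of the closing section for broadly expressed genes near 0 in M07e_C and M07e_KO. A difference in counting is not excluded for these 10 genes, nor for the rises with 0 reads in M07e.

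Of 11 class II genes, 11 were higher in M07e_C. The counts of members higher and lower were 24 and 1 of 27 granulocyte and monocyte genes, 15 and 0 of 19 mast cell, basophil and eosinophil genes, and 16 and 6 of 27 megakaryocyte and platelet proteins. They were 15 and 3 of 20 erythroid genes, 13 and 3 of 16 HOX genes and cofactors, 14 and 5 of 23 stem and progenitor genes, and 19 and 3 of 34 interferon-stimulated genes. They were 6 and 1 of 8 germline genes, 9 and 4 of 16 hedgehog genes and 1 and 9 of 13 imprinted genes. These 11 lists passed camera with the preset correlation (adjusted p from 4.92e-09 to 0.0412). With an estimated correlation the granulocyte and monocyte genes alone passed, with an adjusted p of 0.0469, and the other 10 had adjusted p from 0.0575 to 0.318. CD33 was the granulocyte gene that went down, at 58.27 ± 3.42 against 192 ± 21.9. ITGA2B fell within the platelet list, at 343.7 ± 10.7 against 1439 ± 287, and KIT within the stem cell list, at 268.2 ± 4.8 against 1302 ± 151. PLAGL1, an imprinted zinc finger gene, stood at 0.2271 ± 0.0448 against 97.04 ± 18.5.

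The remaining lists did not pass in that comparison. Members higher and lower were 3 and 10 of 16 genes known from C/G leukaemia, 9 and 2 of 28 DNA methylation genes, 10 and 3 of 25 JAK-STAT targets, 10 and 5 of 20 megakaryocyte and erythroid factors, and 7 and 4 of 16 BCL2 family regulators. They were 10 and 8 of 24 BMP and TGF-beta genes, 8 and 4 of 30 proliferation genes, 4 and 8 of 23 p53 targets, 9 and 6 of 25 ribosome biogenesis genes, 5 and 4 of 12 neural and adhesion genes, 3 and 4 of 10 lymphoid genes, and 7 and 3 of 15 stromal and endothelial genes.

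**Figure D3:**
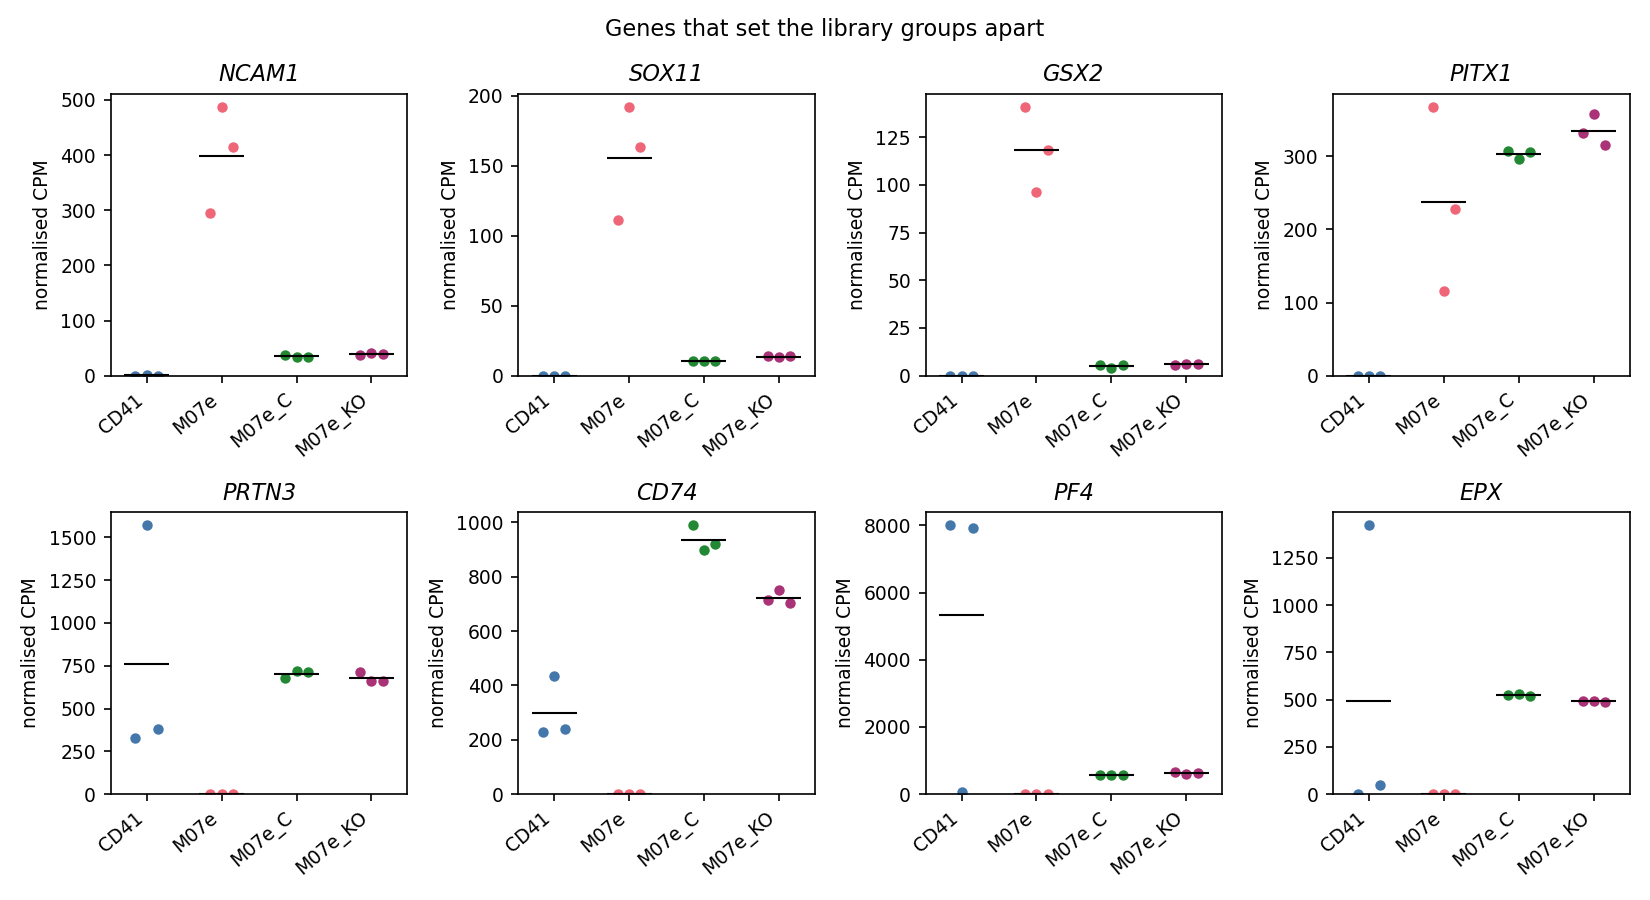
Normalised CPM (vertical axes, linear, from 0) of 8 genes in each of the 3 libraries (points) of 4 groups, with the group mean as a line. NCAM1, SOX11 and GSX2 were highest in the M07e libraries, whereas PRTN3, CD74, PF4 and EPX were near 0 there and PITX1 was at 0 in CD41.

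The libraries labelled M07e_KO were compared with M07e_C to ask which genes differ between libraries labelled DNMT3B knockout and their labelled control. The change was made of a few steep differences in single genes and many small ones. TET1, a DNA demethylase, was at 0.1647 ± 0.106 in M07e_KO and 14.61 ± 1.71 in M07e_C, a log2 difference of -6.44 ± 0.24 (SE). GUCD1 was higher, at 370 ± 14.8 against 15.06 ± 1.61, and C6orf48 at 359.5 ± 12.2 against 24.8 ± 0.376. RPLP2, a ribosomal stalk protein, stood at 2121 ± 55.8 against 756.9 ± 10.8, 2.75-fold higher. Of 13698 genes tested by edgeR, 1286 were higher and 2004 lower in the libraries labelled M07e_KO, and 155 and 338 with an absolute log2 fold change of at least 1. Without M07e_C replicate 3 the higher count was 843.

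The other genes with the largest rise were ATF3, a stress-induced transcription factor (2.95 ± 0.15 on the log2 scale with its SE), FADS3, C17orf58, SLC4A8, ANKS6, CTTN and LRP5L, the last 2.3-fold higher. The other genes with the largest fall were TCTA (-3.79 ± 0.17), SLC25A26, C16orf70, ZFHX3, KCTD13, TMEM167A, RUSC2, TCIRG1 and AGPAT4 (-2.48 ± 0.15). All 20 had edgeR adjusted p of at most 4.9e-08. Replicate values of the groups did not overlap for 38.4% of the tested genes, where chance gives 10%. The replicates of these groups lay close together, with a biological coefficient of variation of 0.055, so small differences pass the test. The labels do not say that these replicates came from separate cultures. A difference between the cultures or clones used for M07e_KO and M07e_C therefore cannot be told apart from the knockout. Several of the 20 genes also differed between M07e_C and M07e: GUCD1 stood at 102.7 ± 18.6 in M07e and RUSC2 had 0 reads there. Against M07e as control the direction turned past the threshold for RUSC2 (log2 difference 10.05, edgeR adjusted p = 0.000205), TCIRG1 (3.20, edgeR adjusted p = 0.00376) and LRP5L (-0.72, edgeR adjusted p = 0.00635), and without passing for C17orf58 (-0.45) and SLC4A8 (-0.37).

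**Figure D4:**
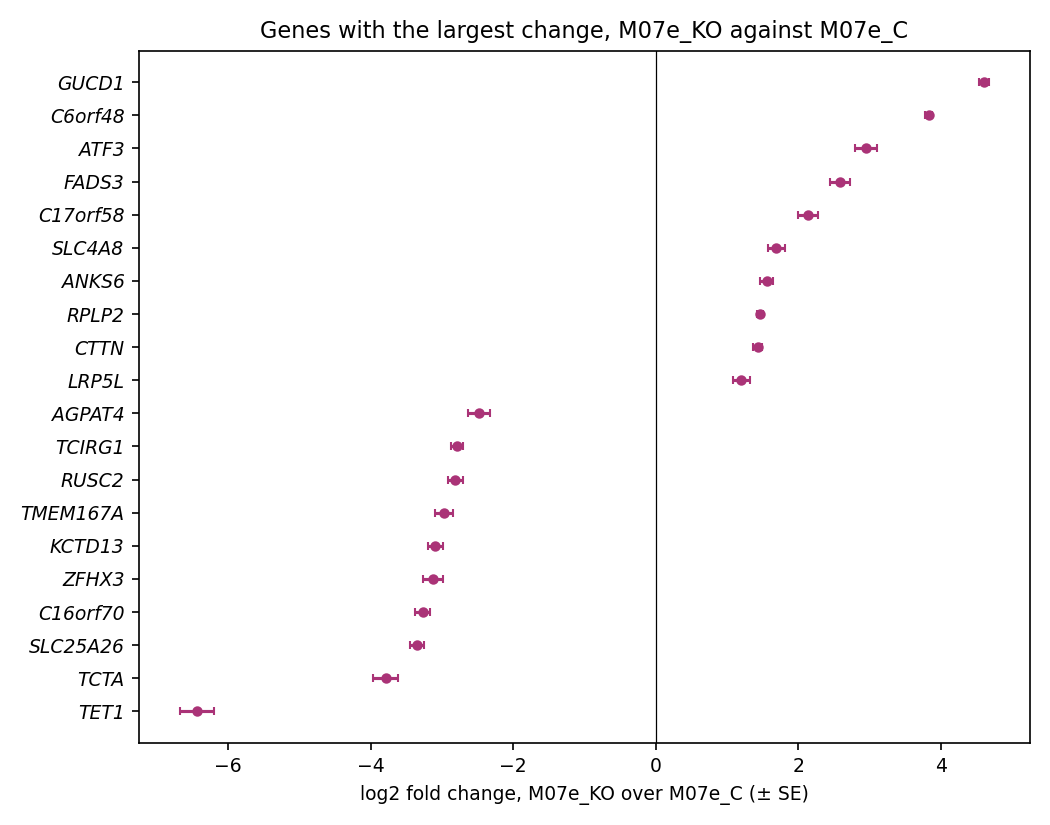
Log2 fold change of M07e_KO over M07e_C (horizontal axis, points, with bars for the standard error) for the 10 protein-coding genes with the largest rise and the 10 with the largest fall. Values run from -6.44 for TET1 to 4.61 for GUCD1.

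No gene list passed camera in the knockout comparison (lowest adjusted p 0.956), although members moved in both directions. With limma's fry, which does not compare a list with other genes, 3 lists passed, all lower. They were proliferation genes (adjusted p = 0.00584), megakaryocyte and erythroid factors (adjusted p = 0.00618) and granulocyte and monocyte genes (adjusted p = 0.0263). Their median log2 fold changes were only -0.03, -0.05 and -0.03. Among 28 DNA methylation enzymes and readers, 6 were higher and 5 lower: besides TET1, UHRF1, which guides maintenance methylation, stood at 187.4 ± 5.55 against 289.4 ± 7.21, while TET2 stood at 42.83 ± 4.6 against 33.29 ± 0.826. Against M07e as control TET2 turned to a log2 difference of -0.31 and did not pass (edgeR adjusted p = 0.179). Of 29 proliferation genes, 3 were higher and 9 lower, such as MCM7 (411.8 ± 15.7 against 541.1 ± 8.73), BIRC5 and CDK1. CDK1 turned to 0.75 log2 units against M07e (edgeR adjusted p = 0.0996), and MCM3, called higher, lost its call when a library was left out (edgeR adjusted p up to 0.0604). Of 20 megakaryocyte and erythroid factors, 2 were higher and 6 lower: RUNX1 stood at 406.1 ± 14.5 against 533.3 ± 14.3 and GFI1B at 137.4 ± 3.54 against 172.7 ± 5.39, whereas ZFPM1 was higher, at 148.3 ± 8.39 against 124.2 ± 3.37, but not against M07e (log2 difference -0.77, edgeR adjusted p = 0.0513). Of 26 megakaryocyte and platelet proteins, 1 was higher and 5 lower, led by GP6, the collagen receptor (36.09 ± 2.33 against 64.07 ± 1.4). The higher one, PLEK, lost its call when a library was left out (edgeR adjusted p up to 0.197).

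Of 33 interferon-stimulated genes 3 were higher and 3 lower, with STAT1 at 167.9 ± 2.78 against 232.1 ± 5.28, but higher by 1.37 log2 units against M07e as control (edgeR adjusted p = 0.000158). Of 23 p53 targets 4 were higher and 4 lower, with CDKN1A, a cell cycle inhibitor, at 175.3 ± 10.4 against 123.6 ± 6.66. CD74 was lower, at 723.1 ± 25.1 against 934.9 ± 47.6, in a class II list with 1 of 11 higher and 2 lower, but higher by 11.97 log2 units against M07e (edgeR adjusted p = 4.05e-06). Of 16 genes known from C/G leukaemia 1 was higher, GLIS2 at 13.76 ± 0.47 against 7.864 ± 0.721, and 2 were lower. Against M07e GLIS2 was lower, with a log2 difference of -3.76 (edgeR adjusted p = 1.16e-05). Members higher and lower were 1 and 6 of 27 granulocyte and monocyte genes, 1 and 5 of 20 mast cell, basophil and eosinophil genes, 2 and 4 of 22 erythroid genes, and 5 and 2 of 22 stem and progenitor genes, where CD34 was lower (45.91 ± 3.59 against 59.85 ± 4.47), though higher by 2.19 log2 units against M07e (edgeR adjusted p = 0.000114). They were 1 and 5 of 24 ribosome biogenesis genes, 1 and 4 of 25 JAK-STAT targets, 3 and 3 of 17 BCL2 family regulators, 1 and 3 of 15 hedgehog genes, 2 and 2 of 12 imprinted genes, and 1 and 1 of 24 BMP and TGF-beta genes. They were 0 and 1 of 18 HOX genes and cofactors, 1 and 2 of 11 neural and adhesion genes, 0 and 1 of 11 lymphoid genes, 1 and 1 of 16 stromal and endothelial genes, and 1 and 0 of 8 germline genes.

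The genes that set M07e apart from CD41 by an absolute log2 fold change of at least 1 were followed in the knockout comparison. Of 9 genes at 50 or more in each M07e library and at most 1 in each CD41 library, the median level in M07e_C was 8.51% of that in M07e (2.74% to 128%). The control thus kept little of the level of these 9 genes in the median. How much M07e_C kept of the full sets, higher or lower, was not measured. The tests of the sets therefore cannot show whether loss of DNMT3B moves a profile that M07e_C may hold only in part. Of 1054 such genes higher in M07e and tested there, 98 were higher and 158 lower in the libraries labelled M07e_KO (24.3% called, against 24% of the other genes, with a limma camera adjusted p of 0.914 over both sets). Of 1373 genes lower in M07e, 132 were higher and 170 lower (22% called, against 24.2% of the other genes, with a limma camera adjusted p of 0.914). With limma's fry both sets passed as lower in M07e_KO (adjusted p = 0.00328 and adjusted p = 0.0217), which for the genes lower in M07e is opposite to the direction from camera. The median log2 fold changes of the sets were 0.001 and 0, against 0.002 for the other genes in each case. Against the libraries titled M07e in place of M07e_C, the same sets moved strongly, down for the genes higher in M07e and up for those lower in M07e, but there the M07e libraries that defined the sets are also the control. The knockout count rested on the choice of control: against M07e it was 4422 higher and 4334 lower, and against M07e and M07e_C together it was 4 and 21. In a single fit of all 12 libraries, 16 genes were higher and 56 lower. M07e_C and M07e differed in 8978 genes, so the count against M07e also holds that difference. Pooling the controls, or adding the CD41 and M07e libraries, brings a wider spread into the test. These counts therefore do not measure the knockout alone.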

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

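The 2 fits with libraries chosen for their values, and those without mitochondrial genes or genes near 0, were added after seeing the data. The cause of a change was not tested, except where fewer libraries or another control explain it by construction. For M07e against CD41 the main counts were 1316 higher and 1543 lower. They moved to 2001 and 940 with library size alone, 2285 and 3454 with DESeq2, 3295 and 3913 in a fit of all libraries, and 590 and 953 with the replicate block. Leaving out each library gave 165 to 3894 higher and 269 to 4317 lower, with the lowest counts without M07e replicate 3 and the highest without CD41 replicate 2. Without replicate 3 of both groups edgeR gave 0 and 0, and 2246 genes had an unadjusted p under 0.05. DESeq2 was not run on those 4 libraries. All 1543 lower calls and 1314 of the 1316 higher calls were also made without CD41 replicate 2. Of 54 named genes, 2 had the same outcome and direction in all alternatives. Since 1 alternative called 0 genes, these 2 had not passed in the main fit either. CD34, which did not pass with all 6 libraries, changed direction to 1.32 (library size alone), 0.31 (replicate block), 1.36 (CD41 replicate 1 alone) and 1.14 (1 library left out) on the log2 scale, and in the last of these it passed as higher in M07e (edgeR adjusted p = 0.0216).

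For the libraries labelled M07e_KO against M07e_C the main counts were 1286 higher and 2004 lower. They moved to 155 and 338 with a log2 fold change of at least 1, 16 and 56 in a fit of all libraries, 4422 and 4334 against M07e, and 4 and 21 against M07e and M07e_C together. Leaving out each library gave 843 to 1429 higher and 1548 to 2072 lower, with the lowest without M07e_C replicate 3. The replicate block gave 986 and 1672. Against M07e, 21 of 54 named genes turned: log2 changes were -0.45 for C17orf58, -0.37 for SLC4A8, -0.72 for LRP5L, 10.05 for RUSC2, 3.20 for TCIRG1, 0.70 for DNMT3B, 2.19 for CD34, -3.76 for GLIS2, -0.31 for TET2, -0.53 for CDCA7, -0.77 for ZFPM1, 5.20 for THBS1, 0.75 for CDK1, 1.37 for STAT1, 11.97 for CD74, 0.13 for WDR12, -0.01 for POLR1B, 5.10 for CPA3, 6.10 for VCAN, -1.42 for CD33 and -2.01 for KIT. Against both controls together 15 turned: -0.05 for LRP5L, 0.27 for DNMT3B, 0.38 for CD34, -2.82 for GLIS2, -0.02 for TET2, -0.21 for CDCA7, -0.35 for ZFPM1, 0.77 for THBS1, 0.09 for CDK1, 0.17 for STAT1, 0.62 for CD74, 0.72 for CPA3, 0.60 for VCAN, -0.81 for CD33 and -1.29 for KIT. With 1 library left out, ITGA2B turned to 0.03 and ITGB3 to -0.01, neither called. PLEK and MCM3 lost their calls with the replicate block. In the fit of all libraries 37 of 54 named genes lost their call. Against both controls together 29 lost it without turning, and the 15 that turned did not pass there either. In all alternatives 8 of 54 had the same outcome and direction.

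For M07e_C against M07e the main counts were 4576 higher and 4402 lower, and 2755 genes were higher with a log2 fold change of at least 1. All other alternatives stayed within 1.5 times, from 3283 to 6098 higher and from 3208 to 6114 lower. Of 34 named genes, 7 lost their call in the fit of all libraries, and 26 of 34 kept call and direction in all alternatives. CBFA2T3, which did not pass, turned to 0.05 without a filter, 0.05 with DESeq2, 0.01 with the replicate block and 0.05 with 1 library left out.

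Gene lists past the threshold numbered 8, 0 and 11 in the 3 comparisons (M07e against CD41, knockout, M07e_C against M07e). An estimated correlation gave 0, 0 and 1, fry gave 8, 3 and 20, and the replicate block gave 8, 0 and 11. With fry the direction turned for stromal and endothelial genes in M07e against CD41 (adjusted p = 0.557), for BCL2 regulators (0.526) and interferon-stimulated genes (0.149) in the knockout, and for BMP and TGF-beta genes (0.41), lymphoid genes (0.00959) and p53 targets (2.08e-05) in M07e_C against M07e. In the knockout, unadjusted values from fry were 0.00164 (lower) for the M07e-higher set and 0.0217 (lower, against higher with camera) for the M07e-lower set. Against M07e camera gave unadjusted values of 7.53e-22 and 4.23e-39, where M07e itself defined the sets. Leaving out a library gave 0.79 to 0.995 for the M07e-lower set, with its direction turned at 0.992 without M07e_C replicate 3.

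Replicate numbers did not pair the libraries. Correlations of same-numbered deviations from the group means were 0.123, 0.121 and -0.065 for M07e against CD41, -0.224, -0.235 and -0.047 for the knockout, and -0.001, 0.001 and 0.019 for M07e_C against M07e, across genes, and not every library correlated best with its own number. The effect of depth was not tested. The floor of 3 counts is highest in CD41 replicate 2, at 0.627 normalised CPM, where mitochondrial genes took 78.54% of the counts. The spread between replicates, with a coefficient of variation of 0.579, limits M07e against CD41.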

Other observations

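The tests of scaling, of mixed RNA, of mitochondrial share and of other cell types below were chosen after the results were seen. Those of overlapping genes, pseudogenes and other splits were set before, but the rule for arguing against the pseudogene explanation was tightened after its result was seen.

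The M07e libraries differed among themselves in single genes. Replicates 1, 2 and 3 had 53.2, 1.99 and 25.4 normalised CPM of SOCS1, a feedback inhibitor of cytokine signalling, and 339, 8.82 and 146 of LGALS1, which encodes galectin-1. SLC40A1, the iron exporter ferroportin, stood at 1.67, 83.8 and 49, IL1A, an inflammatory cytokine, at 1.36, 80.4 and 47, and PCDH19 at 19.8, 225 and 148. Of 4230 protein-coding genes at 50 or more in replicate 1 or 2, 133 differed over 4-fold between them, and replicate 3 lay between for 133 of those 133. These genes were picked for their difference between replicates 1 and 2, and no explanation was tested. Replicate 3 may not be independent of the other M07e libraries, as 84.5% of 10001 genes lay between them there.

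The libraries titled M07e_C differed from those titled M07e in 8978 genes. With library size alone or RLE factors 8977 or more were called, so the choice among these scalings mattered little. The TMM factors over all 12 libraries lay close, however, at 1.16, 1.29 and 1.22 in M07e and 1.17 in each M07e_C library. The count could therefore hardly have moved, and no conclusion on scaling is drawn from it. A mixture of M07e RNA with RNA of other cells was tested under the condition that both were counted the same way. Of 9 genes at 50 or more in each M07e library and at most 1 in each CD41 library, the median level in M07e_C was 8.51% of that in M07e (2.74% for TGM2 to 128% for PITX1), yet 30 of 3014 genes abundant in M07e lay below 0.1 of that share in all 3 M07e_C libraries. Those 30 genes include RPL23, KMT2D, ELAVL1 and SLC39A3, for which a difference in counting stays open. The test therefore cannot decide, and a mixture stays open. A difference between cultures, clones or dates of the line, and libraries of other cells, stay open too. The labels give no batch, and the set of libraries cannot be separated from it.

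Some broadly expressed genes were listed at 0 in M07e_C and M07e_KO. Of 5014 protein-coding genes at 20 or more in the M07e libraries and in CD41 replicates 1 and 3, 32 had at most 3 reads over those 6 libraries, among them RPL23, a ribosomal protein (674.9 ± 12.4 in M07e), KMT2D, ELAVL1 and SLC39A3. Over the 3 M07e libraries, 35 of 5472 genes had at most 3 reads, and over the 3 CD41 libraries 2 of 5242 had. These counts cover fewer libraries than the 6 above. The 35 genes also hold lineage genes such as ELANE, F13A1 and HBD, so they are not a like reverse of the 32. Overlap with another annotated gene was found for 75% of the 32 and 69% of the others (Fisher's exact two-sided p = 0.567), and an annotated pseudogene of the same name for 6.25% and 17.6% (p = 0.104). Neither explanation can be excluded with 32 genes, and a difference in counting or in the genome of the cells stays open.

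CD41 replicate 2 had few megakaryocyte transcripts. With mitochondrial genes left out, the megakaryocyte and platelet list was still at a median of -6.03 log2 units against the mean of the other CD41 libraries, so the mitochondrial share alone does not account for it. A lower share of megakaryocytic cells that raises all other types alike is argued against by the erythroid list, at -4.38, while granulocyte and monocyte genes stood at 4.03 and mast cell, basophil and eosinophil genes at 4.31. A loss of erythroid and megakaryocytic cells together, and a different stage or outcome of the culture, stay open and were not tested. The protocol names a flow cytometry check of CD41+ purity.

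Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real split called 2859, 3290 and 8978 genes in M07e against CD41, the knockout and M07e_C against M07e, and the highest other split called 0 in each, so 1 of 10 splits reached the real count. Every other split mixes the real groups and puts their difference into the spread within groups. Few calls could come from such splits, so no conclusion is drawn from them. The many genes called between M07e_KO and M07e_C do not trace to whole chromosomes: chromosome medians of the log2 fold change lay between -0.013 and 0.056, the highest for chromosome 21.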
